A study of Rattus norvegicus with 12 samples.

How the data were processed

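The series holds polyA RNA and small RNA libraries of neuron-enriched hippocampal cultures from Sprague-Dawley rats (embryonic day 18). Per the labels, vehicle or picrotoxin was applied at 18 DIV for 48 h and RNA was extracted at 20 DIV, with 3 replicates per arm, numbered 3, 10 and 20. The 12 polyA and small RNA libraries form 4 groups of 3. Ribosome-depleted libraries and other cultures of the series were not analysed here.

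For polyA RNA, the submitters' processing notes name STAR 2.3.1z12, Cufflinks 2.2.1, Cuffdiff, Cuffnorm and bedtools 2.22.1, with no role or order and no genome build. The deposited gene table holds a signal per gene and library: fragment counts divided by a size factor of that library. In each library 99.9% of values were whole multiples, within 0.1, of a single step between 0.899 and 1.06, and no length scaling was present. The totals divided by these steps gave about 12840429, 13944781 and 12251406 fragments for control cultures 3, 10 and 20, and 12658344, 11895719 and 11962865 for picrotoxin cultures 3, 10 and 20. FPKM per library had been assumed before the data were examined; since the table holds scaled counts, the filter used the FPKM that the authors gave per group. The authors' Cuffdiff table gives FPKM per group, a log2 fold change, a test statistic (a score), a p-value and a q-value per gene, with status OK for 12405 of 26404 genes. The authors' UTR table gives the lengths in bases of 5' and 3' UTRs per gene model and arm, 11254 entries for 10584 gene names, with replicates pooled; how the ends were called is not stated. Small RNA tables hold raw counts per mature microRNA, as deposited; the tool that made them is not given in the sources used here. Loci are printed as in the authors' table, whose build and start convention are not stated.

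mRNA values were tested with limma 3.58.1 (trend and robust) in R 4.3.3 on log2(value + 1), so that all mRNA fold changes are on that scale. Genes needed an FPKM of 1 or more in at least 1 group, which left 12046. Small RNA counts, 548 microRNAs with 470 in every library, were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood), which left 437; the standard error of a microRNA fold change was taken from the F statistic. Both tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists (25) and microRNA lists (9) were tested with camera (preset correlation 0.01, and again with an estimated correlation), adjusted over the lists. Of 25 gene lists, 14 had a camera adjusted p under 0.05, 4 upward and 10 downward, 0 with an estimated correlation. Of 584 listed symbols, 575 were matched by the table's own symbol, 4 through a reference table and 5 not at all. Symbols of list members are written in rat style where the table prints capitals. Of the tested genes 500 had no symbol.

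The numbers 3, 10 and 20 were taken to pair the libraries. Deviations from the arm means correlated between libraries of the same number (0.41, 0.39 and 0.55 for polyA RNA, 0.33, 0.101 and 0.34 for small RNA), and each library correlated best with its own number. A fit with culture as a block, planned as an alternative before the data were examined, was run for the tests of single genes, single microRNAs and lists, and its value stands beside a result where it changes a call or a count.

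The tests of the report's comparisons, the 25 gene lists and 9 microRNA lists, the alternatives named in this paragraph and the rule for named genes were fixed before the data were examined. Other lists, tests and alternatives were added later and are marked so where they are given. After the data were examined, scaled fragment counts took the place of FPKM per library in the test, and the authors' FPKM per group in the filter and the rule. The rule names Rbfox1, Rbfox2, Rbfox3, Atp2b4 and Dcx; the 6 largest rises and 6 largest falls among called genes with a symbol, an FPKM of 1 or more and groups that do not overlap; and in each list up to 4 called members with the smallest adjusted p, or the 2 most abundant where 0 were called. Some of the genes it chose are withheld and not reported here. For microRNAs it names all members of the miR-129 family and of the miR-132 and miR-212 cluster, the 6 largest changes in each direction, filled by p where fewer passed, and up to 3 called or the 2 most abundant members of the other lists. Alternatives were the block, pseudocounts of 0.1 and 5, no filter or an FPKM of 5, median-ratio and quantile scaling, limma without trend and robust, DESeq2 1.42.0, its size factors, library totals, limma voom, stricter thresholds and the omission of each library.

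Both tests were tried on simulated data built on these libraries. With log2 changes of 0.5 and 1 in 100 genes each (200 in all), limma without a block recovered 12% and 67% with 0 false calls. With the block it recovered 47% and 83% with 11 false calls. Simulated polyA libraries of the same number shared their culture deviation, so the gain with the block was built in and is no evidence of pairing here. Of 60 changed microRNAs, 30 at each of these sizes, edgeR recovered 60% and 96.7%, with 2 false calls. The simulated microRNA counts held no shared culture deviation. UTR correlations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with 100000 permutations; figures used matplotlib 3.10.9. Reads without molecular identifiers are not independent molecules.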

Results

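Hippocampal cultures enriched for neurons, prepared from rats at embryonic day 18, received vehicle or picrotoxin at 18 days in vitro (DIV). Picrotoxin blocks the chloride channel of GABA-A receptors and so raises the activity of the network. After 48 h, at 20 DIV, RNA was taken, and polyA RNA and small RNA were sequenced. The labels number the biological replicates 3, 10 and 20 in both arms and for both kinds of RNA. These numbers are called cultures here, although the labels do not say what they mark. The 12 libraries fell into 4 groups of 3. Scaled fragment totals of the polyA libraries were 12496287, 12534124 and 12982866 in control cultures 3, 10 and 20, and 12304776, 12421518 and 12513949 in picrotoxin cultures 3, 10 and 20. Small RNA counts totalled 9658108, 8654771 and 10009140 in control cultures 3, 10 and 20. In picrotoxin cultures 3, 10 and 20 they totalled 7799363, 7730222 and 10051499.

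The first comparison asked which microRNAs change when network activity is raised for 48 h, with miR-129-5p as the microRNA in the title of the series. miR-129-5p rose 1.41-fold, from 6547 ± 469 to 9252 ± 818 CPM (counts scaled by TMM to a common library size; SD, n = 3). Of the 4 mature microRNAs of the miR-132 and miR-212 cluster, whose transcription CREB is known to drive in active neurons, 3 rose too. miR-155-5p, best known from activated immune cells, rose 5.74-fold from a low level, 6.21 ± 2.25 to 36.1 ± 15.7 CPM (SD, n = 3). No microRNA fell past the threshold in edgeR. Of 437 microRNAs tested, 5 rose and 0 fell at an adjusted p under 0.05 (edgeR, Benjamini-Hochberg). At an unadjusted p under 0.05 there were 43, and DESeq2 called 8, all higher. With culture as a block, 13 rose and 3 fell.

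The 5 microRNAs that rose were miR-155-5p (log2 fold change 2.52, SE 0.36, adjusted p = 0.0293), miR-212-5p (0.66, SE 0.14, adjusted p = 0.0484), miR-212-3p (0.58, SE 0.10, adjusted p = 0.0293), miR-129-5p (0.50, SE 0.09, adjusted p = 0.0293) and miR-132-3p (0.40, SE 0.08, adjusted p = 0.0347). miR-543-3p was 0.50 higher on the log2 scale but did not pass (adjusted p = 0.0640), and it passed with culture as a block (adjusted p = 0.00920). Among those with lower levels, the smallest p values belonged to miR-221-5p, miR-139-5p, miR-138-2-3p, let-7i-3p, miR-29c-3p and miR-544-3p. Their log2 fold changes were -0.44, -0.34, -0.49, -0.31, -0.30 and -0.39, with adjusted p from 0.171 to 0.281. With culture as a block, miR-221-5p, miR-139-5p and miR-138-2-3p passed, with adjusted p of 0.00868, 0.0134 and 0.0479.

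Without a block, each of the 5 microRNAs lost its call when some single libraries were left out, so that fewer libraries were tested. The 3 picrotoxin values of each lay above its 3 control values. With culture as a block and no library left out, miR-155-5p had an adjusted p of 5.9e-10, miR-212-5p 5.2e-05 and miR-212-3p 1.3e-04. In that fit miR-129-5p had 1.4e-04 and miR-132-3p 0.00191. The omissions were run without the block. In edgeR, 0 microRNAs passed without control culture 10, without picrotoxin culture 10 or without picrotoxin culture 20, where 31, 31 and 33 had an unadjusted p under 0.05. Without picrotoxin culture 3, 1 passed, and without control culture 3 or control culture 20, 7 passed each time. miR-129-5p had an adjusted p of 0.251 without control culture 10, 0.171 without picrotoxin culture 3, 0.0779 without picrotoxin culture 10 and 0.136 without picrotoxin culture 20, while its log2 fold change stayed between 0.43 and 0.55. miR-212-3p, miR-132-3p and miR-212-5p lost their calls without the same 4 libraries, with adjusted p of 0.0920 to 0.251, 0.124 to 0.277 and 0.142 to 0.299. miR-155-5p lost its call without control culture 10, control culture 20, picrotoxin culture 10 or picrotoxin culture 20, with adjusted p from 0.0714 to 0.251.

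Of the 3 mature microRNAs of the miR-129 family, 1 rose, 0 fell and 2 did not pass. With p values adjusted over the list alone, 2 rose, and with culture as a block 2 rose. miR-129-2-3p was 4528 ± 178 and 6034 ± 1144 CPM in control and picrotoxin cultures (SD, n = 3; log2 fold change 0.41, adjusted p = 0.197, with the block 0.0479). miR-129-1-3p was 379.7 ± 68.1 and 451.2 ± 43.3 CPM (SD, n = 3; log2 fold change 0.25, adjusted p = 0.573). The family was higher than other microRNAs in camera (adjusted p = 9.3e-05), with adjusted p = 0.130 with an estimated correlation. miR-129-5p is a microRNA on which the study's work centres, so this direction is not independent evidence. Of the 4 mature microRNAs of the miR-132 and miR-212 cluster, 3 rose, 0 fell and 1 did not pass, and 4 rose when adjusted over the list alone, with the block, or in DESeq2. In camera their adjusted p was 1.0e-11, with adjusted p = 0.130 with an estimated correlation. The member that did not pass, miR-132-5p, had a log2 fold change of 0.65 and adjusted p = 0.124, and with culture as a block its adjusted p was 1.2e-05. It stood at 1722 ± 337 and 2701 ± 469.9 CPM (SD, n = 3).

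**Figure D1:**
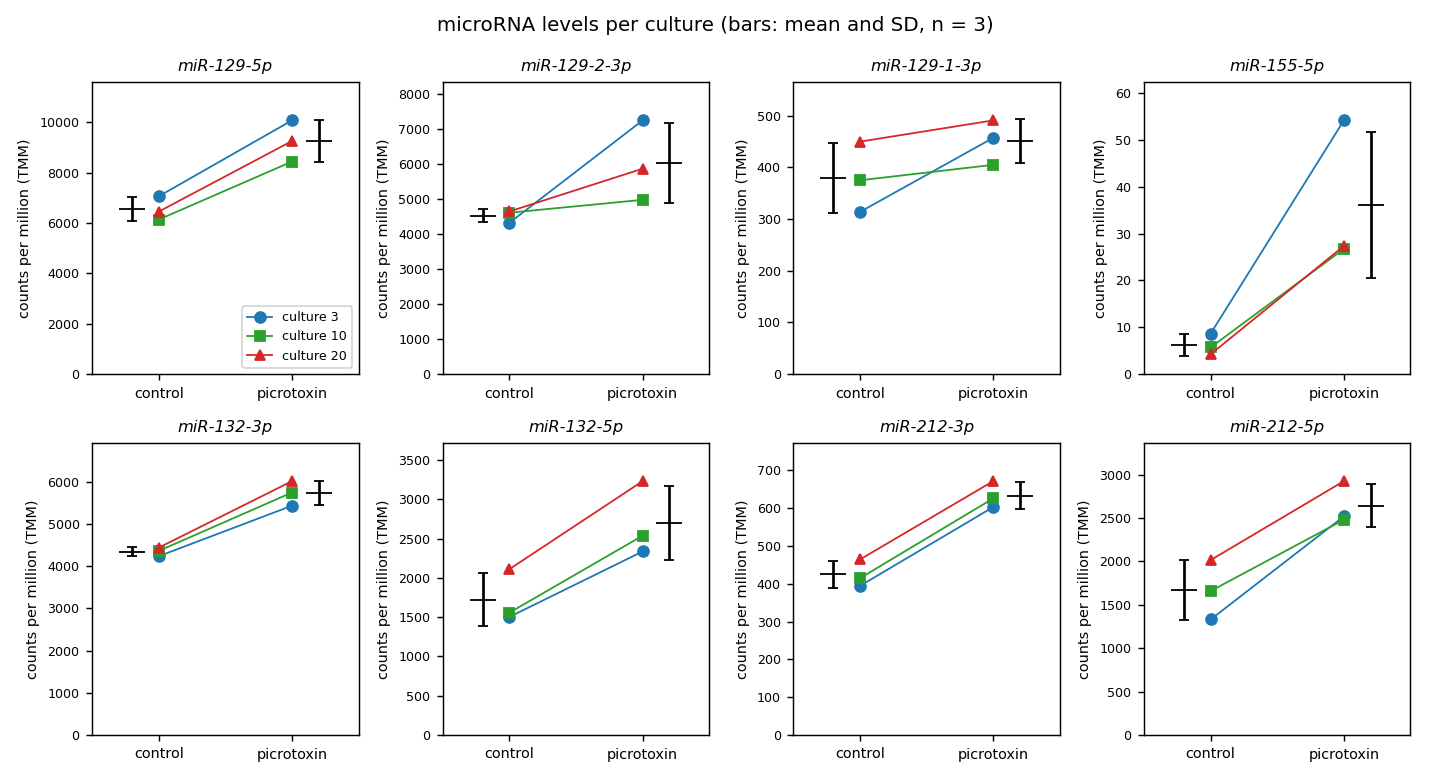
CPM (TMM-scaled counts, linear axis from 0) of the 3 miR-129 family members, miR-155-5p and the 4 members of the miR-132 and miR-212 cluster in control and picrotoxin libraries. Coloured lines join the libraries of cultures 3, 10 and 20, and black bars give mean and SD (n = 3); miR-129-5p lies between 6135 and 7058 in controls and between 8435 and 10070.3 after picrotoxin.

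The other microRNA lists held few calls. Of the 58 tested members of the miR-379 to miR-410 cluster, an imprinted neuronal cluster, 0 passed in edgeR or adjusted over the list alone, with 7 at an unadjusted p under 0.05, 2 in DESeq2 and 2 higher with the block. Its median was 0.01, its mean -0.00 and its camera adjusted p 0.837 upward. Its most abundant members, miR-323-3p and miR-381-3p, had log2 fold changes of 0.07 and -0.04. Of 23 neuron-enriched microRNAs, 0 passed in edgeR or adjusted over the list alone, with 6 at an unadjusted p under 0.05, 0 in DESeq2, and 1 higher and 1 lower with the block (median -0.10, camera adjusted p = 0.146). miR-9a-5p made up 18.2% and miR-128-3p 13.1% of the raw counts of control libraries (mean of 3), with log2 fold changes of -0.01 and 0.17. The level of miR-128-3p differed between controls, from 83380 CPM in culture 3 to 167210 in culture 20.

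In the miR-181 family (8 tested) and the let-7 family (18 tested), 0 members passed in edgeR, adjusted over the list alone, with the block or in DESeq2, with 0 and 2 at an unadjusted p under 0.05. The miR-181 median was 0.01 and its mean -0.00, and its camera test, downward, gave adjusted p = 0.837. miR-181a-5p and miR-181b-5p had log2 fold changes of 0.02 and 0.03, which turned to -0.05 and -0.05 when only library totals were used for scaling. The let-7 family had a median of 0.07 (camera adjusted p = 0.448), with let-7f-5p at 0.12 and let-7i-5p at 0.13. Of 13 astrocyte and reactive glia microRNAs and 5 oligodendrocyte microRNAs, 0 passed in edgeR, adjusted over the list alone, with the block or in DESeq2, with 2 and 0 at an unadjusted p under 0.05. Their medians were 0.04 and -0.02 (camera adjusted p = 0.366 and 0.657). miR-22-3p and miR-24-3p of the first list were at 0.23 and 0.09, and miR-338-3p and miR-338-5p of the second at -0.15 and 0.03, the last at -0.04 with library totals only. Of 3 tested microRNAs of microglia, blood and endothelial cells, miR-155-5p rose, 0 fell and 2 did not pass, and 1 rose when adjusted over the list alone. The median of that list was -0.04, its mean 0.74 and its camera adjusted p 0.146 upward.

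The second comparison asked how the polyA transcriptome changed in the libraries with the same numbers. Atp2b4, which encodes a plasma membrane calcium pump, fell from 1917 ± 239.6 to 684 ± 96.1 scaled fragment counts (SD, n = 3), a 2.81-fold lower level. Rbfox1, Rbfox2 and Rbfox3, which encode neuronal splicing factors, and Dcx, the microtubule-binding doublecortin of young neurons, did not pass the test in limma without a block. Transcripts of neuropeptides, of later activity-regulated effectors and of stress responses included genes that rose, and those of glutamate receptors, postsynaptic scaffolds and calcium handling included genes that fell. Of 12046 genes tested, 201 rose and 195 fell at an adjusted p under 0.05 (limma on log2(value + 1), Benjamini-Hochberg), and 86 of those that rose and 44 of those that fell changed at least 2-fold. With culture as a block, 1162 rose and 1251 fell, and 394 of the 396 calls were among them.

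At an unadjusted p under 0.05 there were 2123 genes. The median log2 fold change over all tested genes was -0.01. The first principal component held 40.9% of the variance and separated the arms, and the second, with 31.9%, set both libraries of culture 20 apart from the rest. The number of calls depended on single libraries: it was 226, 29 and 179 without control culture 3, 10 or 20, and 139 and 894 without picrotoxin culture 3 or 20. Without picrotoxin culture 10, 58 genes rose and 79 fell. Of the 73 genes chosen by the rule for named genes, 53 were called and could lose a call. Among these 53, 14, 43 and 16 lost their calls without control culture 3, 10 or 20, and 28 and 22 without picrotoxin culture 3 or 10. No sign changed among the 396 called genes. Without both libraries of culture 20, 1082 genes passed, and without both of culture 3 or of culture 10, 0 passed in limma, where 1327 and 1046 had an unadjusted p under 0.05.

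Among the genes on which the study's work centres, Atp2b4 (ENSRNOG00000003031, chromosome 13, 55157901 to 55204057) had a log2 fold change of -1.49 (SE 0.13, adjusted p = 0.00171). It kept its call without any single library. Rbfox1 (ENSRNOG00000002827, chromosome 10, 7109395 to 7450683) stood at 2428 ± 302 and 2339 ± 102 scaled fragment counts in control and picrotoxin cultures (SD, n = 3; log2 fold change -0.05, SE 0.10, adjusted p = 0.864), and its log2 fold change was 0.01 without control culture 20. Rbfox3 (ENSRNOG00000003386, chromosome 10, 107153675 to 107174397) stood at 508 ± 37.9 and 397 ± 13.2 (log2 fold change -0.35, SE 0.10), with adjusted p = 0.0917, and with culture as a block 0.00373. Dcx (ENSRNOG00000047712, chromosome X, 113551873 to 113628192) stood at 6216 ± 98.7 and 4868 ± 548 (log2 fold change -0.36, SE 0.09), with adjusted p = 0.0616, and with culture as a block 6.2e-04. Rbfox2 (ENSRNOG00000004688, chromosome 7, 118149475 to 118388515) stood at 924 ± 17.7 and 853 ± 83.3, with a log2 fold change of -0.12 (SE 0.10, adjusted p = 0.601).

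As a list, the 4 genes Rbfox1, Rbfox3, Atp2b4 and Dcx had 0 that rose, 1 that fell and 3 that did not pass; 3 fell when adjusted over the list alone, and 3 with the block. In camera the list was lower than other genes (adjusted p = 0.00177), with adjusted p = 0.216 with an estimated correlation. These genes were chosen by the study, so the direction is not independent evidence. Of the 3 Rbfox genes, 0 passed in limma, with 1 at an unadjusted p under 0.05 and 0 marked by the authors' Cuffdiff. Rbfox3 fell when adjusted over the list alone and with the block (camera adjusted p = 0.126).

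**Figure D2:**
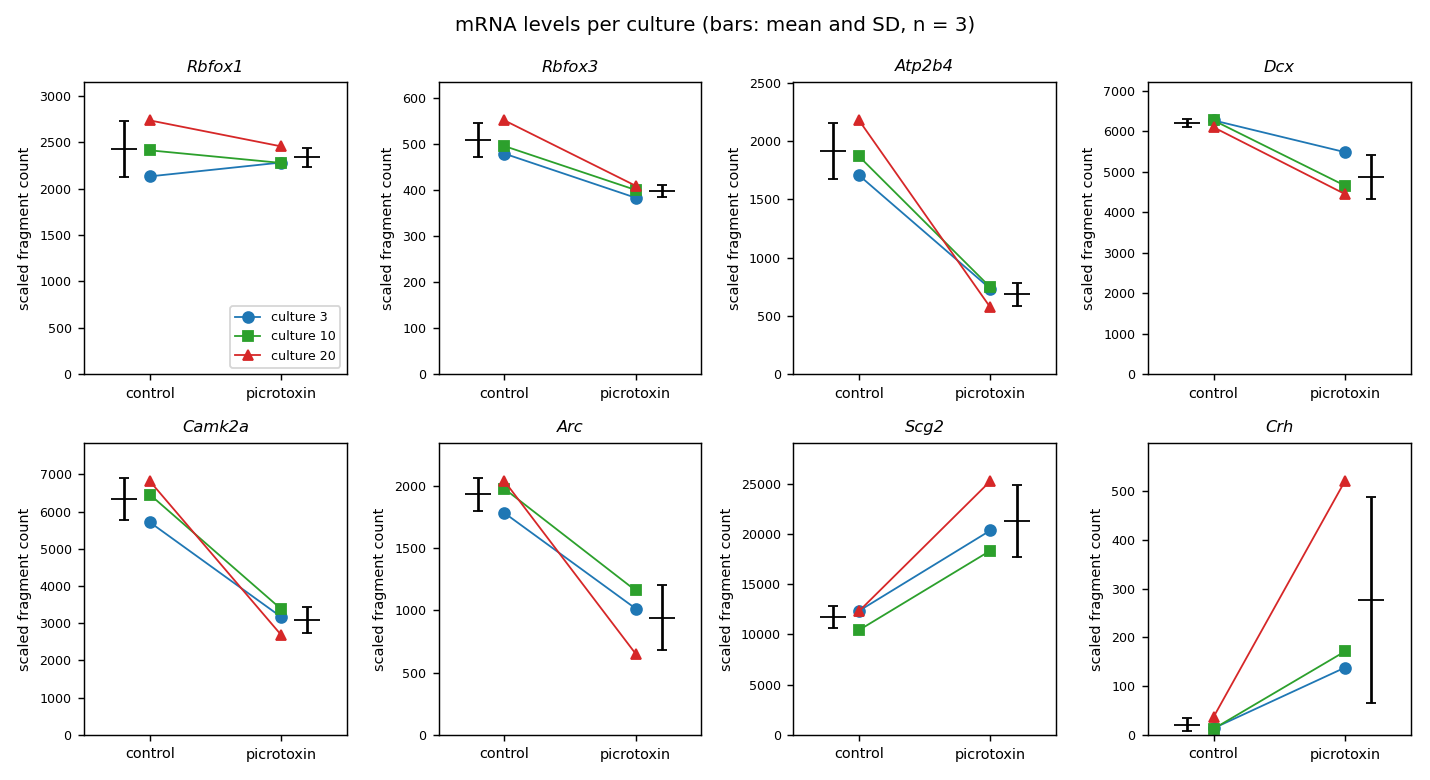
Scaled fragment counts (linear axis from 0) of Rbfox1, Rbfox3, Atp2b4, Dcx, Camk2a, Arc, Scg2 and Crh in control and picrotoxin libraries. Coloured lines join the libraries of cultures 3, 10 and 20, and black bars give mean and SD (n = 3); Atp2b4, Camk2a and Arc lie lower and Scg2 and Crh higher in all 3 picrotoxin libraries.

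The largest rises among genes with a symbol were those of Nmu (neuromedin U, a neuropeptide; log2 fold change 3.70, SE 0.67), Crh (corticotropin-releasing hormone; 3.56, SE 0.51), Lmod3 (leiomodin, an actin nucleator of muscle; 3.34, SE 0.42), Agbl1 (a carboxypeptidase of tubulin; 3.26, SE 0.28) and Arhgdib (a regulator of small GTPases; 3.11, SE 0.24). Their levels in controls were low: Nmu went from 5.26 ± 4.06 to 90.0 ± 68.8, Crh from 21.1 ± 13.9 to 277 ± 212.1 and Arhgdib from 29.8 ± 8.36 to 259.8 ± 48.8 scaled fragment counts (SD, n = 3). Evi2a followed (2.33, SE 0.45), but its locus overlaps those of Nf1 and Omg, at means of 2039 and 1620.4 scaled fragment counts against 25.1, the strand is not stated, and the authors' q for it was 0.662, so its value is uncertain. These 6 rises had adjusted p between 0.00171 and 0.0235. The largest falls were those of PKP2 (plakophilin, a desmosome protein; -1.74, SE 0.30), Nov (a secreted matrix-associated protein; -1.72, SE 0.22), OTOF (otoferlin, a calcium sensor of exocytosis; -1.72, SE 0.14), Calml4 (a calmodulin-like protein; -1.67, SE 0.23), Per3 (a clock gene; -1.64, SE 0.33) and Hpca (hippocalcin, a neuronal calcium sensor; -1.61, SE 0.24). The adjusted p of these falls lay between 0.00171 and 0.0295. Hpca went from 6472 ± 317 to 2233 ± 804 scaled fragment counts, and with culture as a block its adjusted p was 0.0743. Lmod3, Agbl1, Arhgdib and OTOF kept their calls without any single library. Without control culture 10, Nmu, Crh, Evi2a, PKP2, Nov, Calml4, Per3 and Hpca did not pass (adjusted p = 0.0515 to 0.0926), and Nmu, Evi2a, PKP2 and Per3 lost their calls without some of control cultures 3 and 20 and picrotoxin cultures 3 and 10 as well (adjusted p = 0.0530 to 0.104).

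Genes of the glutamatergic postsynapse included many that fell. Of 37 glutamate receptor and auxiliary subunit genes tested, 10 fell, 1 rose and 26 did not pass; adjusted over the list alone 17 fell and 2 rose, and with the block 19 fell and 3 rose. Grin3a (an NMDA receptor subunit, log2 fold change -1.04), Shisa6 (an AMPA receptor auxiliary protein, -0.85), Grm5 (a metabotropic receptor, -0.61) and Gria3 (an AMPA receptor subunit, -0.58) were among those that fell, and Grm8, named after its value was seen as the 1 gene of the list that rose, stood at 0.72. The list median was -0.31 and camera gave adjusted p = 2.2e-05, with adjusted p = 0.301 with an estimated correlation. Of 34 postsynaptic scaffold and adhesion genes, 5 fell, 0 rose and 29 did not pass; adjusted over the list alone 11 fell and 1 rose, and with the block 17 fell and 1 rose. Camk2a, the alpha subunit of the kinase of synaptic plasticity, fell from 6332 ± 563 to 3082 ± 356 scaled fragment counts (SD, n = 3; log2 fold change -1.04, SE 0.10, adjusted p = 0.00248). Iqsec2 (-0.64), Epha4 (-0.60) and Kalrn (-0.58), regulators of dendritic spines, fell as well. That list had a median of -0.22 and a camera adjusted p of 1.9e-07, with adjusted p = 0.216 with an estimated correlation. In the same libraries the 10 astrocyte markers averaged -0.32, the 12 excitatory neuron markers -0.26 and the 8 markers of dividing cells 0.40 on the log2 scale. Camk2a kept its call without any single library. Without control culture 10, Shisa6, Gria3, Grin3a, Grm5, Iqsec2, Kalrn and Epha4 did not pass (adjusted p = 0.0562 to 0.116), nor did Grin3a without picrotoxin culture 3 (0.0562) or 10 (0.0540) and Epha4 without picrotoxin culture 3 (0.0738).

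Calcium handling genes included 10 that fell. Of 32 pumps, buffers and sensors tested, 10 fell, 1 rose and 21 did not pass; adjusted over the list alone 15 fell and 3 rose, and with the block 18 fell and 3 rose. Besides Atp2b4 and Hpca, Slc8a2 (a sodium-calcium exchanger, -0.83) and Camk4 (a nuclear calmodulin kinase, -0.80) fell. The median was -0.30 and camera gave adjusted p = 8.9e-07, with adjusted p = 0.216 with an estimated correlation. The calmodulin genes of this list have near-identical coding sequences, so their separate values are uncertain. In the same libraries astrocyte markers averaged -0.32, excitatory neuron markers -0.26, neuron markers -0.17 and dividing cell markers 0.40. Atp2b4 and Camk4 kept their calls without any single library, and Slc8a2 and Hpca lost theirs without control culture 10 (adjusted p = 0.0666 and 0.0630).

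Other synaptic and channel lists held calls too. Of 24 inhibitory synapse genes, 1 rose, 0 fell and 23 did not pass; adjusted over the list alone 2 rose and 6 fell, and with the block 4 rose and 9 fell (median -0.09, camera adjusted p = 0.0779). Of 34 presynaptic genes, Slc17a6, a vesicular glutamate transporter, rose (0.63), Cplx2, a complexin, fell (-0.51) and 32 did not pass. Adjusted over the list alone 1 presynaptic gene rose and 4 fell, and with the block 4 rose and 14 fell (camera adjusted p = 0.0723). Of 66 voltage-gated and leak channel genes, 4 fell, 0 rose and 62 did not pass; adjusted over the list alone 11 fell and 2 rose, and with the block 20 fell and 12 rose (median -0.07, camera adjusted p = 0.0705). The genes that fell were those of the T-type calcium channels Cacna1g (-0.78) and Cacna1h (-0.67), the sodium channel subunit Scn3b (-0.69) and the calcium channel subunit Cacna2d3 (-0.61). Without control culture 10, none of Slc17a6, Cplx2, Scn3b, Cacna1h, Cacna1g and Cacna2d3 passed (adjusted p = 0.0532 to 0.161). Slc17a6, Cplx2, Cacna1g and Cacna2d3 also lost their calls without some of control cultures 3 and 20 and picrotoxin cultures 3 and 10 (adjusted p = 0.0501 to 0.104).

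Several peptide and late effector transcripts rose, while 4 immediate early genes fell. Of 21 neuropeptide and granin genes, 5 rose, 0 fell and 16 did not pass; adjusted over the list alone 13 rose, and with the block 14 rose. Scg2 (secretogranin) rose from 11691 ± 1096 to 21298 ± 3560 scaled fragment counts (SD, n = 3; log2 fold change 0.86, SE 0.12, adjusted p = 0.00806), and Tac1 (0.93), Vgf (0.70) and Crh rose too. The list median was 0.61 and its camera adjusted p 1.5e-08, with adjusted p = 0.216 with an estimated correlation. Markers of dividing cells averaged 0.40, of astrocytes -0.32 and of excitatory neurons -0.26 in the same libraries. Of 22 late activity-regulated effector genes, 5 rose, 1 fell and 16 did not pass; adjusted over the list alone 8 rose and 2 fell, and with the block 12 rose and 2 fell. Plat (tissue plasminogen activator, 0.97), Nptx2 (a pentraxin that clusters AMPA receptors, 0.58) and Kcnj4 (an inwardly rectifying potassium channel, 0.45) rose, and Lingo1, an inhibitor of neurite growth, fell (-0.39). This list had a median of 0.24 and a camera adjusted p of 0.00165, with adjusted p = 0.327 with an estimated correlation. Tac1 kept its call without any single library, and Scg2, Crh, Vgf, Plat, Nptx2, Kcnj4 and Lingo1 did not pass without control culture 10 (adjusted p = 0.0562 to 0.139). Plat, Nptx2, Kcnj4 and Lingo1 also failed without some of control cultures 3 and 20 and picrotoxin cultures 3 and 10 (adjusted p = 0.0520 to 0.0866).

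Of 31 immediate early genes, 1 rose, 4 fell and 26 did not pass; adjusted over the list alone 4 rose and 5 fell, and with the block 7 rose and 9 fell. Arc, a regulator of AMPA receptor endocytosis, fell from 1933 ± 133.6 to 942 ± 262 scaled fragment counts (SD, n = 3; log2 fold change -1.08, SE 0.18, adjusted p = 0.0164). The transcription factor genes Egr2 (-1.47) and Egr3 (-1.08) fell, and Dusp1, a phosphatase of MAP kinases, rose (0.84). The list median was -0.04 (camera adjusted p = 0.606). Of 24 stress response and cell death genes, 3 rose, 0 fell and 21 did not pass; adjusted over the list alone 11 rose, and with the block 14 rose. They were Cdkn1a (a cell cycle inhibitor, 1.13), Atf5 (a stress transcription factor, 0.64) and Hspa5 (an endoplasmic reticulum chaperone, 0.33). The median was 0.33 and the camera adjusted p 1.2e-06, with adjusted p = 0.216 with an estimated correlation. Beside these stress genes, dividing cell markers averaged 0.40, astrocyte markers -0.32 and excitatory neuron markers -0.26. Dusp1 kept its call without any single library. Arc, Egr2, Egr3, Cdkn1a, Atf5 and Hspa5 did not pass without control culture 10 (adjusted p = 0.0724 to 0.219) or without picrotoxin culture 3 (0.0507 to 0.133). Egr2, Egr3, Atf5 and Hspa5 did not pass without picrotoxin culture 10 (0.0589 to 0.113), Atf5 and Hspa5 without control culture 20 (0.0584 and 0.132), and Hspa5 without control culture 3 (0.0588).

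Sterol and growth lists included genes that fell. Of 24 cholesterol synthesis genes, 4 fell, 0 rose and 20 did not pass; adjusted over the list alone 10 fell, and with the block 12 fell. They included Stard4 (-0.43), a sterol carrier, and the enzyme genes Hmgcs1 (-0.42) and Sc5d (-0.38). The median was -0.22 and camera gave adjusted p = 2.4e-05, with adjusted p = 0.301 with an estimated correlation. Astrocytes make much of the brain's cholesterol. In these libraries the astrocyte markers averaged -0.32, excitatory neuron markers -0.26, neuron markers -0.17 and dividing cell markers 0.40. Whether the mix of cells accounts for the lower sterol genes was not tested. Of 29 immature neuron and axon growth genes, the tubulin genes Tubb2b (-0.64), Tubb3 (-0.53) and Tuba1a (-0.37) fell, 0 rose and 26 did not pass. Adjusted over the list alone 14 growth genes fell and 1 rose, and with the block 16 fell and 2 rose. That list had a median of -0.24 and a camera adjusted p of 5.4e-05, with adjusted p = 0.216 with an estimated correlation. Tubulin genes share near-identical stretches, so the values of single tubulins are uncertain. Tubb2b kept its call without any single library. Tubb3, Tuba1a and the 3 sterol genes Stard4, Hmgcs1 and Sc5d did not pass without control culture 10 (adjusted p = 0.0824 to 0.182), nor without some of control cultures 3 and 20 and picrotoxin cultures 3 and 10 (0.0501 to 0.139).

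In 3 further lists 0 genes passed in limma. Of 34 neuronal RNA-binding protein genes, 6 had an unadjusted p under 0.05, the authors' Cuffdiff marked 2, 0 passed adjusted over the list alone and 8 fell with the block. The list median was -0.14 (camera adjusted p = 0.00654, with adjusted p = 0.543 with an estimated correlation), where neuron markers averaged -0.17, excitatory neuron markers -0.26, astrocyte markers -0.32 and dividing cell markers 0.40. Khdrbs3 had a log2 fold change of -0.42 (adjusted p = 0.147, with the block 6.2e-04) and Stau2 of -0.09. Of 18 microRNA biogenesis and silencing genes, 2 had an unadjusted p under 0.05, 0 were marked by Cuffdiff, 0 passed adjusted over the list alone, and 1 rose and 2 fell with the block. Cnot7 stood at -0.13 and Prkra at -0.23 (camera adjusted p = 0.0662). Of 19 glycolysis genes, 2 had an unadjusted p under 0.05, 0 were marked by Cuffdiff, 0 passed adjusted over the list alone, and 2 rose and 1 fell with the block. Gapdh stood at 0.06 and Aldoa at 0.07, and the list median was 0.07 (camera adjusted p = 0.138).

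Markers of cell types were examined as levels. Of 12 neuron markers, Tubb3 fell, 0 rose and 11 did not pass. Adjusted over the list alone 1 fell, and with the block 2 fell. All 12 neuron markers lay below 0 (median -0.15, camera adjusted p = 0.0118, with adjusted p = 0.543 with an estimated correlation). Of 12 markers of excitatory pyramidal and granule neurons, Camk2a and Neurod1 (-0.60) fell, 0 rose and 10 did not pass; adjusted over the list alone 5 fell, and with the block 5 fell and 1 rose. Of these 12 excitatory markers, 4 lay above 0 and 8 below. Their median was -0.22 and camera gave adjusted p = 0.0402, with adjusted p = 0.235 with an estimated correlation and 0.0513 with the block. Of 17 interneuron markers, Calb2 fell (-0.48), 0 rose and 16 did not pass; adjusted over the list alone 2 rose and 1 fell, and with the block 6 rose and 1 fell (median 0.00, camera adjusted p = 0.393). Of 10 astrocyte markers, 0 passed in limma, with 1 at an unadjusted p under 0.05, 2 marked by Cuffdiff, 1 lower adjusted over the list alone and 5 lower with the block. All 10 were below 0, with a median of -0.32 (camera adjusted p = 0.0174, with adjusted p = 0.576 with an estimated correlation); Slc1a2 stood at -0.16 and Glul at -0.11. Neurod1 and Calb2 lost their calls without control culture 10 or 20 or picrotoxin culture 3 or 10, and Calb2 also without control culture 3 (adjusted p = 0.0656 to 0.184).

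The last marker lists held 0 calls in limma, in the authors' Cuffdiff or adjusted over the list alone. Of 8 markers of dividing cells, 2 had an unadjusted p under 0.05 and 2 rose with the block, and all 8 were above 0, with a median of 0.34 (camera adjusted p = 0.00611, with adjusted p = 0.216 with an estimated correlation). Pcna stood at 0.06 and Birc5 at 0.30. Of 5 oligodendrocyte and precursor markers, 2 had an unadjusted p under 0.05, and with the block Cnp (0.28, adjusted p = 0.0278) rose and 1 fell (camera adjusted p = 0.606). Of 4 markers of endothelial, mural and fibroblast cells, 0 had an unadjusted p under 0.05 and 1 rose with the block; Sparc stood at 0.09 and Dcn at 0.18 (camera adjusted p = 0.586). Of 16 microglia and macrophage markers, only 2 reached the level needed for testing, with 0 at an unadjusted p under 0.05 and 0 with the block: Lyz2, at -0.08, and Cd68, at 0.47 (camera adjusted p = 0.606).

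**Figure D3:**
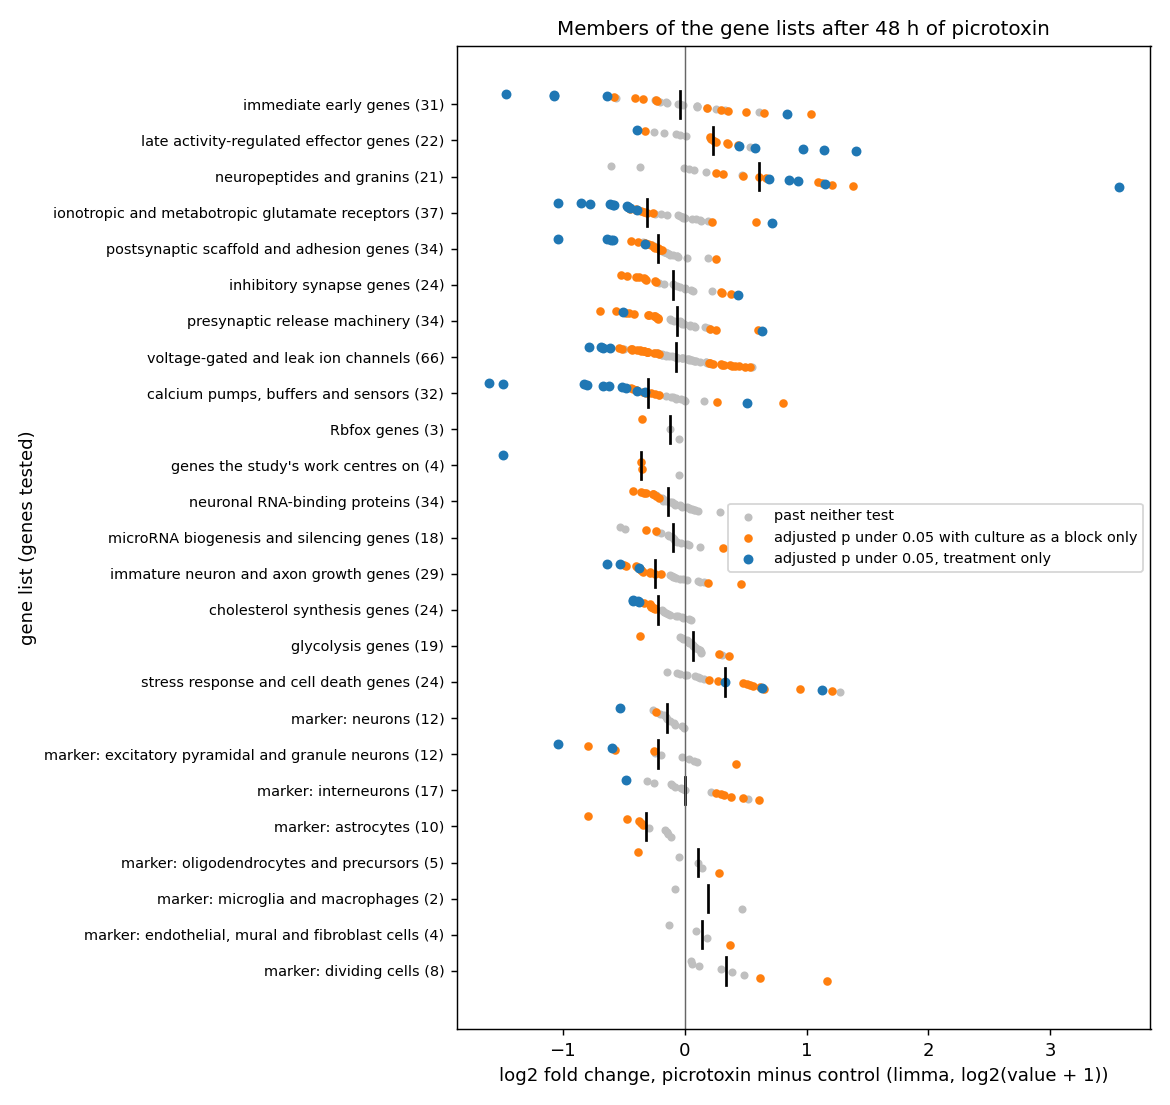
Log2 fold change (picrotoxin minus control, limma on log2(value + 1)) of each tested member of the 25 gene lists; numbers in brackets give the members tested and black bars the list medians. Blue points passed adjusted p under 0.05 without a block and orange points only with culture as a block; neuropeptide genes have a median of 0.61 and glutamate receptor genes one of -0.31.

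The third comparison set these calls beside the authors' own test. Their Cuffdiff table marked 932 genes, 477 higher and 455 lower with picrotoxin, among them Atp2b4 (authors' FPKM 41.4 and 14.8 in control and picrotoxin cultures, q = 0.00155) and Dcx (54.8 and 42.9, q = 0.0331). Rbfox1 (46.6 and 44.9, q = 0.911), Rbfox3 (41.0 and 31.9, q = 0.110) and Rbfox2 (40.2 and 37.0, q = 0.771) were not marked. Of the 396 genes called here, all but 17 were marked by the authors too, and each of these had the same direction in both. With culture as a block, 889 of the 908 genes that the authors marked among those tested here were called.

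The fourth comparison described the lengths of untranslated regions (UTRs), where sites for microRNAs and Rbfox proteins lie. The authors gave 1 length per gene model and arm, with no replicates. For Atp2b4 the 3' UTR was 4245 bases in both arms, for Dcx 7653 bases in control and 7633 in picrotoxin cultures, for Rbfox1 2667 and 2567, and for Rbfox3 1290 and 1106. Of 9868 genes with a 3' UTR length in both arms, 37.7% had equal lengths, 29.0% a longer and 33.3% a shorter one after picrotoxin, with a median difference of 0 bases; 435 genes differed by at least 500 bases. These include lengths of 0, in 1 arm only for 261 genes and in both arms for 313. Of 9294 genes with lengths above 0 in both arms, chosen after the values were seen, 36.7% had equal, 29.4% had longer and 33.9% had shorter ones. Across 9240 tested genes, longer 3' UTRs in controls went with lower log2 fold changes (Spearman rho = -0.19, permutation p = 1e-05, the smallest that 100000 permutations can give). Of 4 equal groups by length, the one with the shortest 3' UTRs (median 107 bases) had a median log2 fold change of 0.04 and the one with the longest (median 2702 bases) one of -0.06. The length of the whole locus gave a similar relation across all tested genes (Spearman rho = -0.15). Its shortest and longest of 4 groups had medians of 0.04 and -0.06, so the relation does not single out 3' UTRs. At an FPKM of 5 or more, rho was -0.18 across 7866 genes (permutation p = 1e-05), and with lengths above 0 in both arms it was -0.18 across 8844 genes (permutation p = 1e-05). Genes are not independent replicates, and the 3 correlations with the 3' UTR length in controls were the ones computed in this family.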

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

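Of the settings below, the omission of both libraries of a culture and the use of only 3' UTR lengths above 0 were chosen after the data were seen. The number of mRNAs called was 396 (201 higher, 195 lower). It was within 1.5 times of that (300 to 483) with other pseudocounts, filters and scalings, and 270 at 1.5-fold or more, where 113 were lower. It was 2413 (1162 higher, 1251 lower) with the block, 159 (94 and 65) in limma without trend and robust, 71 (35 and 36) at an adjusted p under 0.01 and 932 (477 and 455) in the authors' table. With libraries left out it ranged from 0 to 1082, and with single libraries left out from 15 to 378 higher and 14 to 516 lower. Of the 1082 without both libraries of culture 20, 595 were lower and the rest higher. Both counts of 0, without culture 3 or culture 10, came with 1327 and 1046 at an unadjusted p under 0.05 in limma. The block kept 394 of the 396 calls. Of the called genes named, only Hpca lost its call with it. Apart from the values printed with the results, it changed no other call of a gene named in the report or of the 25 planned gene lists.

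The number of microRNAs called, 5, was 16 (13 higher, 3 lower) with the block, 8 (8 higher) in DESeq2, 3 (3 higher) with DESeq2 size factors, 2 (2 higher) with library totals and 0 (0 higher) in edgeR at an adjusted p under 0.01, and 5, 4 and 5 with no filter, a stricter filter and limma voom. The 2 calls with library totals include only 1 of the 5; miR-212-5p was the one kept. With libraries left out the number ranged from 0 to 14, with single libraries from 0 to 7 higher and 0 to 1 lower. The 14, without both of culture 3, were 9 higher and 5 lower, and the 8 without both of culture 20 were all higher. In these microRNA omissions, control culture 10, picrotoxin culture 10, picrotoxin culture 20 and both libraries of culture 10 gave the 0s, with 31, 31, 33 and 25 at an unadjusted p under 0.05 in edgeR.

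With an estimated correlation, 0 of 14 gene lists and 0 of 2 microRNA lists stayed past the threshold. The adjusted p was 0.216 for neuropeptides, postsynaptic, calcium, study, immature neuron, stress and dividing cell genes, 0.235 for excitatory markers, 0.301 for glutamate receptors and cholesterol synthesis, 0.327 for late effectors, 0.543 for RNA-binding proteins and neuron markers, and 0.576 for astrocyte markers. Both microRNA families had 0.130. With the block, excitatory markers had 0.0513 in camera. The rotation test fry, planned beside camera, asks whether a list moves at all and not whether it differs from other genes. Its adjusted p was 0.0215 to 0.0263 for neuropeptides, postsynaptic, calcium, study, immature neuron, stress and dividing cell genes and excitatory markers. For the others of the 14 gene lists it was 0.0574 to 0.325. The authors' table held 573 genes at q under 0.01 and 540 at 1.5-fold or more.

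Directions turned only for genes and microRNAs that had not passed. Lyz2 was 0.048 in the authors' table, and with library totals miR-181a-5p, miR-181b-5p and miR-338-5p were -0.050, -0.046 and -0.037. With libraries left out, log2 fold changes ranged from -0.14 to 0.043 for Rbfox1, -0.023 to 0.11 for Gapdh, -0.0051 to 0.15 for Aldoa, -0.42 to 0.54 for Lyz2, -0.096 to 0.28 for Sparc and -0.031 to 0.16 for Pcna. They ranged from -0.043 to 0.15 for miR-323-3p, -0.11 to 0.0047 for miR-381-3p, -0.054 to 0.044 for miR-9a-5p, -0.084 to 0.39 for miR-128-3p, -0.041 to 0.067 for miR-181a-5p, -0.039 to 0.061 for miR-181b-5p and -0.13 to 0.12 for miR-338-5p. Of all single comparisons of named items with a setting, mRNAs gave 1115 with the same call, 315 that lost and 11 that gained one and 12 that turned; microRNAs gave 383, 39, 20 and 17. The cause was not tested for any of these changes, except that omissions and stricter thresholds use fewer libraries or calls. No scaling moved the median of all mRNAs by over 0.1. The correlation of 3' UTR length with log2 fold change, -0.19, was -0.18 at an FPKM of 5 or more and -0.18 with lengths above 0. A test of microRNA and Rbfox sites in 3' UTRs was not run, since it needs sequence, and other pseudocounts had no use for microRNA counts.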

Other observations

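In this part, the tests of the authors' scaling, of neuron loss, of excitatory neuron loss, of microglial mRNAs, of muscle genes, of clock genes, of a rise of miR-155-5p brought wholly by more cells that carry miR-142 and of other splits of the libraries were chosen only after the results were seen, as were the 6 gene lists of the next paragraph. The use of only UTR lengths above 0 was chosen later too. Tests of gene length, of blood and microglia microRNAs and of UTR coverage were written before.

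Energy and matrix genes were examined as further groups. Of 88 oxidative phosphorylation genes, 71 lay above 0, 1 rose, 0 fell and 87 did not pass; with the block 7 rose (camera adjusted p = 0.00604, with the block 0.00367, with adjusted p = 0.856 with an estimated correlation). The gene that rose was Cox6a2, a subunit form of heart and muscle, from a mean of 24.5 to 62.2 scaled fragment counts. Of 21 extracellular matrix genes, Spon1, a secreted adhesion protein, fell from a mean of 979 to 487.1 scaled fragment counts and 0 rose; with the block 6 fell and 1 rose (camera adjusted p = 0.312). In limma 0 of 87 ribosomal protein genes passed, with 1 at an unadjusted p under 0.05, 0 in the authors' Cuffdiff and 1 higher with the block (camera adjusted p = 0.781). In limma 0 of 11 MHC class I and interferon-response genes passed, with 1 at an unadjusted p under 0.05, 0 in Cuffdiff and 1 higher with the block (camera adjusted p = 0.383).

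Lmod3 among the largest rises raised the hypothesis that striated muscle genes rise more widely. Of 8 such genes tested, Cryab, a small heat shock protein (1.10), and Klhl41, a sarcomere protein (1.04), rose and 0 fell, and with the block 3 rose and 2 fell; camera gave adjusted p = 0.0487, 0.141 with the block, and adjusted p = 0.406 with an estimated correlation, which leaves it open. Per3 raised the hypothesis of a wider fall of clock genes. Of 19 tested, Tef (-0.44) and Arntl (-0.52) fell and Nfil3 rose (0.67), with the block 4 fell and 5 rose, 9 lay above and 10 below 0, and camera pointed upward (adjusted p = 0.781, and adjusted p = 0.965 with an estimated correlation), which gives a wider fall no support.

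The lower level of glutamate receptor and postsynaptic genes was seen as a median log2 fold change of -0.25 over 71 genes. Of these, 59 lay below 0, and 16 were called in limma, 15 of them lower. In camera with an estimated correlation, the receptor list had adjusted p = 0.301 and the postsynaptic list 0.216. Locus length as the whole cause is argued against, since 0% of 10000 random lists matched on locus length and level had a median as low (lowest -0.15). The matching used 10 bins of each property, and genes were drawn singly. Genes of both lists varied together (estimated correlation 0.16 in each), which the draws ignored, so the 0% is no p-value for the lists. The random lists had a median of -0.05 against -0.01 for all genes, so length and level may account for a part. They were not matched on 3' UTR length. The authors' scaling as 1 factor per library moves all genes alike, so it cancels from a difference between genes. The median of the receptor and postsynaptic genes lay 0.22 below that of all genes (mean difference -0.22 over the 3 pairs, SE 0.03). These lists were taken up because they lay below other genes, so this check of the scaling restates that and decides nothing more. Rescaling moved both medians too little to decide anything. Fewer neurons in the picrotoxin cultures would raise the markers of all other cells alike, if levels per cell stayed the same. Neuron markers averaged -0.17, all 12 below 0. Dividing cell markers (8 tested of 18) averaged 0.40 (SE 0.08), those of endothelial, mural and fibroblast cells (4 of 18) 0.13 (SE 0.09). Those of microglia (2 of 16) averaged 0.19 (SE 0.14) and of oligodendrocytes (5 of 16) 0.02 (SE 0.06). Astrocyte markers (10 of 15) averaged -0.32 (-0.13, -0.32 and -0.49, SE 0.10). Astrocyte and dividing cell markers thus lay 0.72 apart (SE 0.15 over the 3 pairs). In limma 0 genes of either list passed, and levels per cell were not measured. Fewer neurons therefore stay open, as do more dividing cells. Fewer excitatory neurons together with fewer astrocytes may account for the lower lists and stay open. Excitatory markers without Camk2a averaged -0.19 (SE 0.01 over the 3 pairs), and their difference from the lists was 0.04 (SE 0.03). The excitatory markers were mixed, which an SE over pairs does not show: of the 12 with Camk2a, 4 lay above 0 and 8 below. Lower transcript levels within neurons under picrotoxin stay open as well, untested.

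The rise of miR-155-5p, from 95, 50 and 40 counts in control cultures 3, 10 and 20 to 431, 202 and 255 in picrotoxin cultures, might come from more microglia or blood cells. Such cells carry abundant miR-142, whose 2 forms had 2 to 5 counts per library and differed by -0.21 on the log2 scale over the 3 pairs; miR-223 was not listed. More cells bringing the whole rise would take the 13 counts of the controls to 64.3, and 9 were found. The log2 change was 2.71 below that of miR-155-5p (difference -2.71, SE 0.25), which argues against such cells as the whole source. The sum of 14 microglial mRNAs, 2.70 to 19.4 scaled counts per library, was higher by 0.94 on average (1.22, 1.49 and 0.12), 1.55 below the change of miR-155-5p (difference -1.55, SE 0.53). Both sets of counts are low, so a smaller gain of microglia stays open, as does more miR-155-5p in each of these cells. A rise of miR-155-5p in neurons or astrocytes under picrotoxin stays open, untested.

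The authors' 3' UTR lengths were longer after picrotoxin in 78 and shorter in 29 of 162 genes called higher, and longer in 38 and shorter in 79 of 177 genes called lower. The table holds 3' lengths of 0, in 1 arm only for 261 genes; values below 0 were left out. With lengths above 0 in both arms, 60 genes called higher were longer and 29 shorter, and 38 called lower were longer and 72 shorter. UTR ends read further out where coverage is higher may explain this, but the test left it open. Across genes not called, changes in length followed the log2 fold change at the 5' end too (Spearman rho = 0.050, permutation p = 2e-05) beside 0.09 at the 3' end. With lengths above 0 these values were 0.021 (permutation p = 0.051) and 0.064. In the lowest of 4 equal groups by FPKM, rho was 0.26 at the 3' end and 0.16 at the 5' end, and in the highest group 0.02 (permutation p = 0.46) and -0.03. With lengths above 0 the lowest group had 0.163 and 0.060. A change in the choice of polyA site under picrotoxin was not tested.

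For other groupings, the 6 polyA libraries have 10 splits into 3 and 3, and only 1, the real one, reached 396 calls, with a highest other count of 0. For small RNA the real split gave 5 and the highest other 0, so again 1 of 10 splits. With 10 splits, too few for a share under 0.05, nothing more can be said. Of these splits 4, the real one included, part the libraries of every culture, and the others keep both libraries of some culture together.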
